A study of Homo sapiens with 18 samples.

How the data were processed

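Total RNA from 18 samples of 22Rv1 and LNCaP cells was hybridised to Affymetrix Human U133 Plus 2.0 arrays, a 1-colour platform with biotin label, after a 3' in vitro transcription labelling protocol. Per the labels, cells grew in RPMI medium with 10% serum, and lentiviral lines were made with polybrene at 5 µg/mL and selection on puromycin at 5 µg/mL. The overexpression vector carried the full-length coding cDNA. The protocol names 2 ONECUT2 shRNA clones and a non-target control plasmid. The titles of the arrays labelled ONECUT2 shRNA carry a number that ends the identifier of 1 of these clones, and the titles of the arrays labelled scramble carry another number, which ends neither. The treatment label of the control cells reads vehicle. The labels give no batch.

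The deposited values are log2 expression values that the authors made with GCRMA, which corrects background by probe sequence, quantile-normalizes and summarizes probe sets. The version, and whether all 18 arrays were normalized together, are not given in the sources used here. The table held 54675 probe sets, 62 of them platform controls. Probe sets were named through the gene table supplied: 41097 mapped to exactly 1 symbol (41043 with the symbol updated through the gene identifier), 1801 to several and 11721 to none. For each of 19777 genes the single-symbol probe set with the highest mean over all arrays was used. Genes were tested if it exceeded a log2 value of 4 on at least 3 arrays, which left 12159. SYP failed the filter.

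All 18 arrays entered 1 model in limma 3.58.1 under R 4.3.3, with a mean for each of the 6 groups and 12 residual degrees of freedom. Empirical Bayes moderation used trend and robust options, and p-values were adjusted by Benjamini-Hochberg over genes within each comparison. Genes with an adjusted p under 0.05 were called. The 6 comparisons were overexpression against control in each line, ONECUT2 shRNA against scramble, the difference of the overexpression effects between lines, scramble against 22Rv1 control, and LNCaP control against 22Rv1 control. Overlaps of calls used one-sided Fisher exact tests over the genes tested, beside the number that independent lists would share. The ONECUT2 probe sets other than the gene-level one were read from a fit of every probe set. Scramble against control shares arrays with other comparisons, so no overlap with it was read.

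Before the data were examined, 19 gene lists were fixed, 3 of which are not reported here, although totals of list calls include them. The others were luminal, basal and neuroendocrine markers, neuronal and axon genes, HNF, gut and liver lineage genes, hypoxia, TGF-beta and SMAD, epithelial-mesenchymal transition, mitosis, G1-S and DNA replication, p53 targets, interferon-stimulated, stress and unfolded protein response, cholesterol and fatty acid synthesis, stromal markers, and leukocyte and endothelial markers. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over lists within a comparison. The comparisons, the model, the alternatives and the naming rule were also fixed before the data were examined. For each of the 3 main comparisons the rule named ONECUT2, the 8 largest rises and 8 largest falls whose 3 treated arrays all lay on 1 side of the 3 controls, up to 3 called members of each list by smallest p, and FOXA1, KLK3, PEG10, CHGA and HNF4G whatever their result. Each other comparison gave its 5 largest changes each way, and each overlap its 8 largest. Uncharacterised, antisense and open-reading-frame symbols were left out of the rankings. Some named genes are described in counts only.

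Where all 3 arrays of the lower group read under 4, a change is given as at least the difference from 4, with the adjusted p of the model. ONECUT2 probe sets, differences between lines and fits without 1 array keep their fitted values. Probe sets are read as gene levels with no correction for copies of a gene family. The beta-actin and GAPDH control probe sets gave 3' minus 5' differences, compared by an exact permutation test. The model was tested on simulated data with 12159 genes, each given its observed spread pooled over the 6 groups, and 66 or 67 genes changed per size. For log2 changes of 0.5, 1 and 2 it recovered 49.3%, 85.1% and 98.5% in 22Rv1 overexpression, and 31.3%, 73.1% and 92.4% in LNCaP overexpression. For ONECUT2 shRNA it recovered 29.9%, 85.1% and 98.5%, and for the difference between lines 10.4%, 62.7% and 87.9%. Of simulated calls 4.91%, 3.68%, 4.70% and 7.76% were false in that order. Every group of a gene had the same simulated spread, so these rates do not cover groups of unequal spread, such as LNCaP overexpression. All other genes were simulated without a change, whereas 60.8%, 62.2%, 29.6% and 44.7% of genes were called in the real comparisons, in that order. The cutoff set by the adjustment thus differs, and these rates do not carry over to the real calls. The number of arrays, 3 per group, limits precision.

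Alternatives were no filter, a log2 filter of 6, quantile normalization or median centring of the deposited values, the mean of a gene's probe sets, every probe set on its own, array weights, no trend or robust option, only the groups compared, a replicate block, adjusted p under 0.01, a log2 change of at least 1, and leaving out each array in turn. The 22Rv1 control in place of scramble was added after the data were seen.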

Results

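The study measured messenger RNA in 2 human prostate cancer cell lines whose level of ONECUT2, a homeobox transcription factor of the HNF6 family, had been changed. 22Rv1 grew out of a prostate carcinoma xenograft, and LNCaP came from a lymph node metastasis. Total RNA from 18 samples was hybridised to 18 expression arrays, 3 in each of 6 groups. 4 groups were 22Rv1 cells: control, ONECUT2 overexpression, scramble shRNA and ONECUT2 shRNA. The other groups were LNCaP control and LNCaP ONECUT2 overexpression. Median log2 values per array lay between 3.26 and 3.34, and 38.3% to 40.0% of probe sets exceeded a log2 value of 4. The number of arrays limits the precision. The labels do not say that the 3 arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical. Arrays of one group correlated at 0.996 or more across all 54675 probe sets, except LNCaP overexpression, where the lowest value was 0.975. Its replicate 1 stood apart, with a mean correlation of 0.969 with the LNCaP controls, against 0.948 for replicate 2 and 0.953 for replicate 3. Log2 changes are given with their standard error from the model, which pools the spread of a gene over all 6 groups. KLK3 thus had an error of 0.67 in both lines. Its SDs were 0.24 and 0.14 in 22Rv1 control and overexpression, and 0.005 and 2.22 in those of LNCaP. Such errors can be too wide in 22Rv1 and too narrow in LNCaP.

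ONECUT2 itself was read by 5 probe sets, whose positions on the transcript are not given in the sources used here. The one with the largest rise had a fitted rise of 12.9-fold in LNCaP overexpression (log2 change 3.68 ± 0.38, adjusted p = 4.11e-07), with 5.23, 7.17 and 7.43 on the 3 arrays. The LNCaP control arrays read 2.99, 2.74 and 3.04, all under 4, so this size rests partly on background. In 22Rv1 overexpression the same probe set had a fitted rise of 2.19-fold (1.13 ± 0.38, adjusted p = 0.0175). It read 4.78, 4.14 and 4.21 there, against 3.05, 3.44 and 3.25 in control, so this rise lies near background. The probe set with the highest mean stood for the gene in the gene-level model. It was higher by 0.54 ± 0.16 in 22Rv1 overexpression (adjusted p = 0.00702) and by 0.66 ± 0.16 in LNCaP overexpression (adjusted p = 0.00153). Other ONECUT2 probe sets were mixed: one rose by 1.16 ± 0.15 in 22Rv1 overexpression (adjusted p = 3.83e-06) and by 0.53 ± 0.15 in LNCaP overexpression (adjusted p = 0.00524). Another fell by 0.97 ± 0.24 in 22Rv1 overexpression (adjusted p = 0.00234) and differed by 0.23 ± 0.24 in LNCaP (adjusted p = 0.415), and the last differed by -0.07 and 0.11 (0.69 and 0.511). The 22Rv1 call of the gene-level probe set was lost when arrays were centred on their median (0.36, adjusted p = 0.0607). Against the labels, ONECUT2 was 4.15-fold higher in the arrays labelled ONECUT2 shRNA than in the arrays labelled scramble (2.05 ± 0.16, adjusted p = 7.33e-08). The probe sets that rose and fell in 22Rv1 overexpression (1.16 and -0.97) both went the same way as it there, by 1.97 and 1.74. The others differed by 0.17 (adjusted p = 0.792), the one with the largest LNCaP rise, and 0.12 (adjusted p = 0.584). That gene-level probe set was lower in the arrays labelled scramble than in the 22Rv1 control (-1.41, adjusted p = 8.84e-06) and higher in the arrays labelled ONECUT2 shRNA than in that control (0.65, adjusted p = 0.0265). Against that control the probe set at 1.97 was higher in the arrays labelled ONECUT2 shRNA as well (1.37, adjusted p = 5.24e-05), while the others did not differ, at -0.27 for the one with the largest LNCaP rise, 0.01 and 0.02 (adjusted p = 0.792, 0.988 and 0.971). Group names follow the labels, and every direction drawn from the shRNA groups carries this discrepancy.

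**Figure D1:**
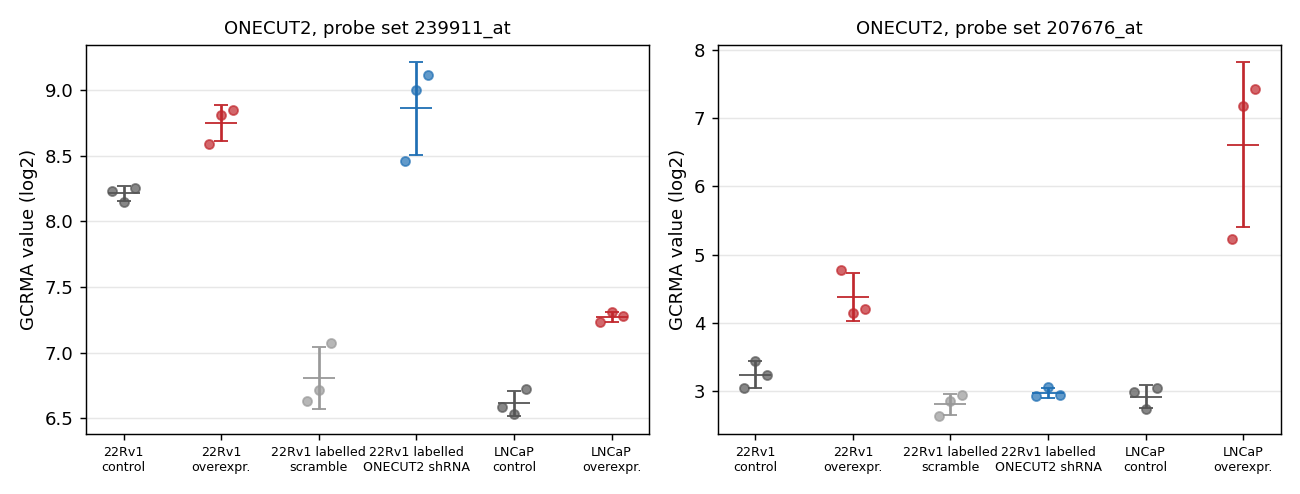
GCRMA log2 values of 2 ONECUT2 probe sets on each array (points), with the mean and SD of each group of 3 (lines). The probe set with the highest mean (left) is lowest among the 22Rv1 groups in the arrays labelled scramble, and the one with the largest rise in LNCaP (right) is highest in LNCaP overexpression, where its 3 arrays read 5.23, 7.17 and 7.43.

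The first comparison asked which genes change when ONECUT2 is overexpressed in 22Rv1. Cell cycle genes fell as a group: all 25 measured members of the mitosis list were lower, as were 23 of 24 members of the G1-S and DNA replication list. MKI67, the proliferation antigen Ki-67, was 11.9-fold lower (-3.57 ± 0.16, adjusted p = 3.42e-11). In the HNF, gut and liver list 7 of 11 genes were lower, and in cholesterol and fatty acid synthesis 15 of 20. Both of those calls were lost, with adjusted p = 0.0707 and adjusted p = 0.331 with an estimated correlation. KLK3, which encodes prostate-specific antigen, was 8.14-fold lower (-3.02 ± 0.67, adjusted p = 0.00116). NCAN, a proteoglycan of brain matrix, was among the largest rises (at least 30.5-fold, adjusted p = 1.51e-13).

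Across 12159 genes, 4440 were higher and 2952 lower in 22Rv1 overexpression than in control, and 2896 of these 7392 differed by at least 2-fold. The largest rises, each with all 3 overexpression arrays above all 3 controls, began with LIX1L (53.3-fold) and IFI6 (at least 40.5-fold), an interferon-induced gene. EGR3, an immediate early transcription factor, rose 44.9-fold and SOCS3, a brake on cytokine signalling, at least 14.8-fold. GJA3, a connexin, rose 40.9-fold, the histone gene H2AC6 40.7-fold, and CYP26B1, which breaks down retinoic acid, at least 20.9-fold. GJA1, a gap junction protein, fell most (48.5-fold lower, -5.60 ± 0.30). TFPI, an inhibitor of coagulation, was at least 13.8-fold lower, ALDH1A1, a retinal dehydrogenase, 19.9-fold, and RGS1, a regulator of G protein signalling, at least 6.12-fold. TRHDE, a peptidase, and GPM6A, a neuronal membrane glycoprotein, were 18.8- and 18.2-fold lower, AVPR1A, a vasopressin receptor, at least 13.3-fold, and CDH6, a cadherin, fell by 4.17 ± 0.16 in log2.

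Within the gene lists for 22Rv1 overexpression, the mitosis list had a median of -2.51 (camera adjusted p = 4.35e-15, and 0.0207 with an estimated correlation). CCNA2, a cyclin, fell by 2.68 and FOXM1, a transcription factor of mitotic genes, by 2.80. The G1-S and DNA replication list had a median of -1.96 (adjusted p = 4.35e-15, and 1.55e-04 with an estimated correlation). MCM2, a subunit of the replicative helicase, fell by 2.66, CDC45, a replication factor, by at least 2.06 and RFC4, of the clamp loader, by 1.48. In the HNF, gut and liver list 7 of 11 were lower and 1 higher (median -1.64, adjusted p = 9.05e-04, and adjusted p = 0.0707 with an estimated correlation). SPINK1, a trypsin inhibitor, fell by 3.52, APOH, a plasma apolipoprotein, by at least 2.15, VIL1, the microvillus protein villin, fell by 2.27, and the transcription factor HNF4G by 1.64. In cholesterol and fatty acid synthesis 15 of 20 were lower and 0 higher (median -0.90, adjusted p = 1.61e-04, and adjusted p = 0.331 with an estimated correlation). IDI1 and FDPS of isoprenoid synthesis fell by 1.08 and 0.76, and ELOVL6, a fatty acid elongase, by 1.15. The counts of these 4 lists were the same when adjusted over the list alone.

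On the same 22Rv1 overexpression arrays, the 3' minus 5' difference of the beta-actin control probe sets was 8.06 ± 0.70 (SD, n = 3), against 4.11 ± 0.41 in the 22Rv1 controls. An exact two-sided permutation test of that difference gave p = 0.1, the smallest that 3 arrays against 3 allow. The GAPDH control probe sets gave -0.43 ± 0.13 and -0.70 ± 0.09. The 5' control probe set of ribosomal RNA read 5.50 ± 0.59 against 8.93 ± 0.19. The middle one read 4.58 ± 0.27 against 8.38 ± 0.22 and the 3' one 5.60 ± 0.18 against 7.34 ± 0.07. The lower ribosomal RNA signal was thus not confined to the 5' end. These differences go with every gene group described for 22Rv1 overexpression.

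**Figure D2:**
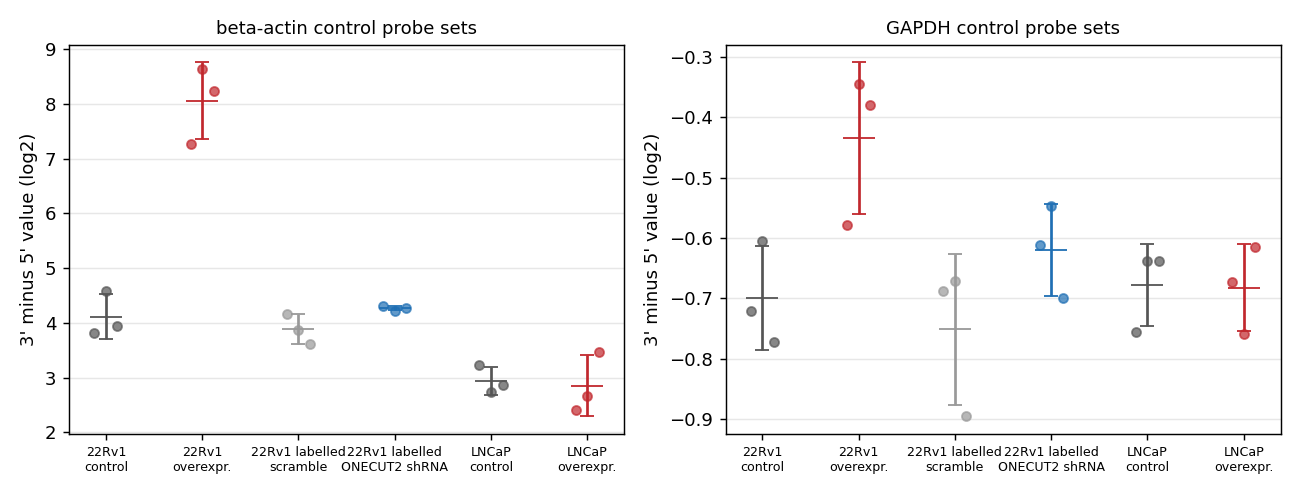
Difference between the 3' and 5' control probe sets (log2) of beta-actin and GAPDH on each array (points), with group mean and SD (lines, n = 3). For beta-actin the 22Rv1 overexpression arrays lie between 7.28 and 8.65, above every other array.

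In 22Rv1 overexpression SPDEF, an Ets factor of secretory epithelium, fell by 2.40, CREB3L4 fell by 1.65, GATA2 by 1.00, and FOXA1, a forkhead factor, by 1.87. The other lists described did not pass. Luminal markers included 8 lower and 4 higher of 15 (adjusted p = 0.0948). KRT19, a keratin, fell by 3.84, while EPCAM and CDH1, epithelial adhesion proteins, rose by 1.00 and 0.79. Of 18 neuroendocrine markers 5 were higher and 6 lower (adjusted p = 0.663). NKX2-1, a lung and thyroid transcription factor seen in neuroendocrine tumours, rose by at least 2.64. SRRM4, a neural splicing factor, fell by 2.55 and CELF3, an RNA-binding protein, by 2.48. CHGA, the granule protein chromogranin A, was higher by 0.78 ± 0.29 (adjusted p = 0.026). It lost its call without control replicate 1 (0.71, adjusted p = 0.079) or 3 (0.79, adjusted p = 0.0534), without overexpression replicate 1 (0.42, adjusted p = 0.179) and under both rescalings (0.64 and 0.60). PEG10, a retrotransposon-derived gene, differed by -0.40 ± 0.25 (adjusted p = 0.182). That error takes in an SD of 0.77 in LNCaP overexpression, against 0.09 and 0.05 in 22Rv1 control and overexpression, so a change is not excluded.

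Neuronal and axon genes in 22Rv1 overexpression went both ways, 7 higher and 6 lower of 17 (adjusted p = 0.893). L1CAM, a neural adhesion molecule, rose by 3.84, NEFL, a neurofilament, by at least 2.25, and MAPT, which encodes tau, by 1.82. Interferon-stimulated genes counted 11 higher and 3 lower of 21 (adjusted p = 0.0948), with HERC5 up by 2.15 and MX1 by 1.88. Hypoxia genes counted 11 higher and 6 lower of 24 (adjusted p = 0.58). P4HA2, a collagen hydroxylase, rose by 2.73 and ADM, adrenomedullin, by 3.10. p53 targets counted 9 higher and 2 lower of 19 (adjusted p = 0.58), TGF-beta and SMAD genes 7 and 6 of 16 (0.993), and epithelial-mesenchymal transition genes 5 and 2 of 15 (0.773). Stress and unfolded protein genes counted 14 higher and 9 lower of 24 (0.716), basal markers 1 and 1 of 3 (0.976) and stromal markers 1 and 2 of 5 (0.295). Adjusted over the list alone, 6 neuroendocrine markers, 12 interferon-stimulated and 8 TGF-beta genes were higher and 7 neuronal genes lower, with other counts the same. Median, mean and test differed in sign for the neuroendocrine list (-0.01, 0.12, down) and the neuronal list (-0.01, 0.02, up). Of the leukocyte and endothelial markers 0 passed the filter. Centring the arrays moved the median change of all genes from 0.10 to -0.07, and the share of calls that were higher from 60.1% to 46.0%.

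The second comparison asked the same of LNCaP. All 25 mitosis genes were lower there too, with a median of -5.62, and 24 of them fell further than in 22Rv1 by the test of the difference (list adjusted p = 1.22e-13, and 0.0274 with an estimated correlation). TOP2A, a topoisomerase of dividing cells, fell (-6.86 ± 0.17, adjusted p = 1.11e-14). KLK3 was 103-fold lower (-6.68 ± 0.67, adjusted p = 4.93e-07, with -7.96 without overexpression replicate 1 and -5.93 without replicate 2) and TMPRSS2, a transmembrane protease, 27.1-fold lower (-4.76 ± 0.16, adjusted p = 4.16e-13). Of 19 p53 targets 17 were higher: CDKN1A, the cyclin-dependent kinase inhibitor p21, was 10.9-fold higher (3.44 ± 0.14, adjusted p = 2.9e-12).

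Among 12159 genes, 4150 were higher and 3407 lower in LNCaP overexpression than in LNCaP control, 7557 in all and 3093 of them by at least 2-fold. MBD3L2, a relative of methyl-CpG-binding proteins, had the largest fitted rise (at least 483-fold). PRAMEF12 and PRAMEF11, germline genes of the PRAME family, rose at least 97.7- and 112-fold, and the pseudogene FRG2EP at least 50.4-fold. These 4 belong to multi-copy families, so a probe set may read more than 1 copy. PNMA2, a neuronal antigen of paraneoplastic disease, rose at least 65.8-fold, and NID1, a basement membrane protein, at least 36.1-fold. ALDH5A1, a mitochondrial enzyme of GABA breakdown, rose at least 25.1-fold, and IER3, an early response gene, at least 51.8-fold. RRM2, a subunit of ribonucleotide reductase, had the largest fitted fall (377-fold lower, -8.56 ± 0.73), and TM4SF1, a tetraspanin-like surface protein, was at least 127-fold lower. The kinetochore gene NUF2 was at least 91.6-fold lower. NDC80, of the same complex, had a fitted fall of 199-fold, with 4.01, 1.13 and 1.87 on the 3 overexpression arrays. Fitted falls were 221-fold for DLGAP5 of the spindle, 173-fold for the recombination factor MND1, 157-fold for SHCBP1, and 156-fold for ANLN, which encodes the cytokinesis protein anillin. On overexpression replicates 2 and 3, RRM2, NDC80, DLGAP5, MND1 and SHCBP1 read under 4, so their folds rest partly on background. Without overexpression replicate 1 the fitted log2 changes were larger: 9.05 for FRG2EP (7.78 with all arrays), 8.32 for IER3 (6.90), 7.78 for NID1 (7.20), -9.92 for RRM2, -8.76 for DLGAP5, -8.47 for NDC80, -8.35 for ANLN, -8.32 for MND1 and -7.98 for SHCBP1. Except for ANLN, every array of the lower group then read under 4, so these sizes rest partly on background. Without replicate 2 the fitted changes were 7.05 for FRG2EP, 6.15 for IER3, -7.62 for RRM2, -7.03 for NDC80, -6.80 for MND1 and -6.68 for ANLN, and without replicate 3 that of IER3 was 6.23.

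In the LNCaP lists, mitosis genes gave adjusted p = 3.16e-21, and 0.00345 with an estimated correlation. CCNA2 fell by 4.78 and FOXM1 by 4.87. G1-S and DNA replication genes were lower in 22 of 24 and higher in 1 (median -3.19, adjusted p = 1.88e-14, and 2.09e-04 with an estimated correlation). MCM2 fell by 4.06, RFC4 by 2.69 and RRM1, of ribonucleotide reductase, by 1.96. SPDEF fell by 4.69, CREB3L4 by 4.62 and FOXA1 by 3.02 (-3.95 without overexpression replicate 1). p53 targets counted 17 of 19 higher and 0 lower (median 1.59, adjusted p = 7.31e-07, and 9.03e-04 with an estimated correlation). TP53I3, a p53-induced oxidoreductase, rose by 4.67 and TIGAR, a regulator of glycolysis, by 1.64. Adjusted over the list alone, 18 p53 targets were higher and 23 replication genes lower, and the mitosis list kept its counts.

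On these LNCaP overexpression arrays, 78 genes were over 9 in 22Rv1 overexpression and under 4 in LNCaP control. Of those, 34, 30 and 6 were still under 4 on replicates 1, 2 and 3, and on replicate 3 their median lay -4.13 from the 22Rv1 overexpression level. Without replicate 3 the count of changed genes was 6888, and these list calls held. The beta-actin difference was 2.85 ± 0.56 in LNCaP overexpression and 2.94 ± 0.25 in LNCaP control (SD, n = 3).

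The other lists described did not pass in LNCaP overexpression. Neuroendocrine markers counted 4 higher and 0 lower of 18 (adjusted p = 0.521), and 3 adjusted over the list alone. ENO2, neuron-specific enolase, rose at least 23.9-fold, PEG10 12.7-fold and TUBB3, a neuronal tubulin, 1.28-fold. CHGA differed by 0.43 ± 0.29 (adjusted p = 0.203), and was called without LNCaP overexpression replicate 1 (0.73, adjusted p = 0.0172). Neuronal genes counted 7 higher and 3 lower of 17 (0.579), with NEFL up by 3.48 and L1CAM by at least 1.34. Interferon-stimulated genes counted 12 higher and 5 lower of 21 (0.0678). IFIT3 and IFIT1, antiviral effectors, rose by 4.36 and 3.41, and ISG15, a ubiquitin-like modifier, rose 9.21-fold. Luminal markers counted 4 higher and 8 lower of 15 (0.129), with KRT19 down and CD24, a surface sialoglycoprotein, up by 3.49. In the HNF, gut and liver list 2 were higher and 3 lower of 11 (0.809). UGT2B17, a glucuronosyltransferase, read 9.05, 1.75 and 3.73 on the 3 overexpression arrays against 9.68 in control, a change of -4.84 that was -6.94 without replicate 1 and -3.29 without replicate 2. TTR, transthyretin, fell by at least 0.20. LGALS4, a gut galectin, differed by 0.54 between groups that both read under 4 (3.01 and 2.47). HNF4G, also under 4 in both groups, was higher by 0.50 ± 0.18 (adjusted p = 0.0247), a call lost without control replicate 1 (0.47, adjusted p = 0.0676) or 3 (0.47, adjusted p = 0.067) and without overexpression replicate 1 (0.42, adjusted p = 0.0507) or 3 (0.37, adjusted p = 0.117).

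Hypoxia genes in LNCaP overexpression counted 7 higher and 8 lower of 24 (adjusted p = 0.798), with P4HA2 up by 3.07 and ALDOC, an aldolase, by 2.79. TGF-beta and SMAD genes counted 8 and 4 of 16 (0.521). ID1 and ID2, inhibitors of differentiation, rose by 2.02 and 2.11. Transition genes counted 7 and 5 of 15 (0.798): VIM, vimentin, rose by 2.67, while SNAI2, the transcription factor Slug, fell by 3.87. Cholesterol and fatty acid genes counted 3 and 8 of 20 (0.427). IDI1 rose by 1.35, and SREBF1, a lipogenic transcription factor, fell by 1.63. Stress genes counted 9 and 7 of 24 (0.986), basal markers 0 and 0 of 3 (0.916) and stromal markers 1 and 2 of 5 (0.97). COL1A1, a collagen, rose by 3.64. Adjusted over the list alone, 8 transition genes were higher, with the other counts the same. Median, mean and test differed in sign for the HNF list (0.04, -0.73, down), hypoxia (-0.09, 0.05, down), stromal markers (-0.22, 0.48, down) and basal markers (0.00, -0.34, down).

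**Figure D3:**
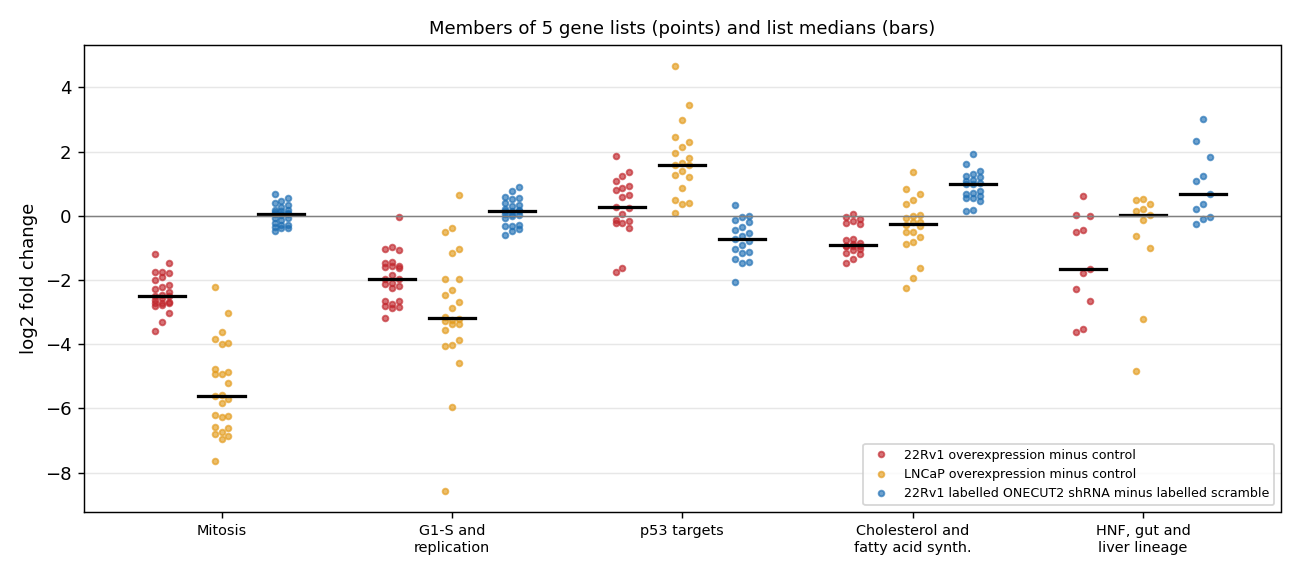
Log2 fold change of each measured member of 5 gene lists (points) and list medians (bars) in 22Rv1 overexpression, LNCaP overexpression and the arrays labelled ONECUT2 shRNA against those labelled scramble. Mitosis genes have medians of -2.51, -5.62 and 0.07 in that order.

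Genes called in both lines went largely the same way. EGR3, the heme-degrading enzyme HMOX1, the desaturase SCD5, IFI6, GJA3, the AP-1 component FOS, the transporter SLC22A17 and the homeobox factor CUX2 led the shared rises. HMOX1 rose by 4.89 ± 0.34 in 22Rv1 and 5.99 ± 0.34 in LNCaP, or 6.60 without LNCaP overexpression replicate 3, and FOS by at least 3.92 and 2.70. TFPI, the phosphatase PTPRR, butyrylcholinesterase BCHE, myoglobin MB, the phosphoinositide phosphatase INPP4B, MKI67, the BRCA1 partner BARD1 and the kallikrein KLK2 led the shared falls. INPP4B fell by 3.58 and by at least 4.31, and KLK2 by 3.53 and 6.94 (-7.94 without LNCaP overexpression replicate 1). KLK2 read 3.18 and 3.41 on LNCaP overexpression replicates 2 and 3, so its LNCaP values rest partly on background. Of 5043 genes called in both lines, 4367 (86.6%) changed in the same direction, 2649 up and 1718 down, where independent lists would share 1515 and 827 (one-sided Fisher exact odds ratios 6.13 and 6.20). Another 676 went in opposite directions. Fold changes in both lines had a Pearson correlation of 0.595 and a Spearman correlation of 0.578 across genes, which are not independent replicates. The beta-actin (8.06 against 4.11) and ribosomal RNA (5.50 against 8.93) differences in 22Rv1 go with these counts. So do the 78 genes over 9 in 22Rv1 overexpression and under 4 in LNCaP control, of which 6 stayed under 4 on LNCaP replicate 3. Without LNCaP replicate 3 the same-direction count was 4111.

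The overexpression effect itself differed between lines for 5432 genes, 2197 with a more positive effect in LNCaP and 3235 with a more negative one. MBD3L2, PRAMEF12, PRAMEF11, ALDH5A1 and FRG2EP had the largest positive differences, from 8.58 ± 0.28 down to 6.61 ± 0.95. TM4SF1, the nuclease DNASE2B, RUNX2, a Runt transcription factor, RRM2 and FCAMR, an immunoglobulin receptor, had the largest negative ones, from -7.91 ± 0.18 to -6.13 ± 0.16. Of these 10 genes 9 had a group mean under 4, so their sizes and order rest partly on values near background, and FRG2EP gave 7.88 or 5.89 without LNCaP overexpression replicate 1 or 2. Mitosis genes were more negative in LNCaP for 24 of 25 (adjusted p = 1.22e-13, and 0.0274 with an estimated correlation), and p53 targets more positive for 15 of 19 (2.44e-07, and 0.00105 with an estimated correlation). G1-S genes were more negative for 16 of 24 (0.00315), while HNF, gut and liver genes were more positive for 6 of 11 (0.00315) and cholesterol genes for 8 of 20 (0.0403). Those 3 calls were lost, with adjusted p = 0.067, 0.0835 and 0.609 with an estimated correlation. These counts were the same when adjusted over the list alone. In the HNF list, SPINK1, APOH, VIL1 and HNF4G had means under 4 in both LNCaP groups, so no fall could be seen there. The difference of that list thus rests partly on background. Centring the arrays moved the share of positive calls from 40.4% to 58.8%. These differences subtract the 22Rv1 effect, whose arrays carry the beta-actin (8.06 against 4.11) and ribosomal RNA (5.50 against 8.93) differences, while in LNCaP these were 2.85 against 2.94 and 12.90 against 13.26.

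The third comparison set the arrays labelled ONECUT2 shRNA against those labelled scramble, to ask what silencing changes in 22Rv1. ONECUT2 messenger RNA ran against these labels. In the arrays labelled ONECUT2 shRNA, 5 of 11 HNF, gut and liver genes and 15 of 20 genes of cholesterol and fatty acid synthesis were higher, calls lost with adjusted p = 0.0706 and adjusted p = 0.215 with an estimated correlation. Of 19 p53 targets 14 were lower. CYP2C8, a hepatic cytochrome P450, was 24.0-fold higher (4.59 ± 0.21, adjusted p = 2.41e-10), and LGR5, a stem cell receptor for R-spondins, 16.4-fold higher (4.04 ± 0.21, adjusted p = 7.69e-10). H2AC6 was 40.9-fold lower (-5.36 ± 0.13, adjusted p = 1.55e-13). Mitosis genes counted 3 higher and 0 lower of 25, with a median of 0.07 (adjusted p = 0.672), and 1 adjusted over the list alone.

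Of 12159 genes, 1630 were higher and 1963 lower in the arrays labelled ONECUT2 shRNA, and 799 of these 3593 differed by at least 2-fold, 459 higher and 340 lower. Centring the arrays moved the share of calls that were higher from 45.4% to 52.3%, so the majority direction is not fixed. Next among the rises were LHFPL6 (12.4-fold), the adrenergic receptor ADRA2A (12.4-fold), CDH6 (10.6-fold), the kallikrein KLK11 (10.5-fold), DDC, which makes dopamine and serotonin (10.1-fold), and the hepatic glucuronosyltransferase UGT2B4 (at least 4.32-fold). Among the falls, GJB2, the gap junction protein connexin 26, was 40.5-fold lower, KLK3 21.2-fold, the linker histone H1-2 21.1-fold and BASP1, a membrane-bound signalling protein, 20.7-fold. The histone gene H2BC21 was 18.7-fold lower, the germ cell gene ASZ1 at least 13.3-fold and CGA, the alpha chain of glycoprotein hormones, at least 10.4-fold. The 5' control probe set of ribosomal RNA read 9.17 ± 0.43 in the arrays labelled ONECUT2 shRNA and 7.47 ± 0.19 in the arrays labelled scramble (SD, n = 3), a difference that goes with every gene group of this comparison. The middle and 3' ones differed the same way (8.51 against 6.84, and 6.88 against 5.90). Set against the 22Rv1 control instead, a comparison added after the ONECUT2 values were seen, the arrays labelled ONECUT2 shRNA differed in 542 genes (286 higher, 256 lower). There CYP2C8 differed by 0.47 (adjusted p = 0.257), LGR5 by 0.72 (0.0637) and KLK3 by -1.68 (0.196), while H2AC6 fell by 2.33, H2BC21 by 1.70 and CDKN1A by 1.18. For KLK3 these groups read 5.64 ± 0.13 and 7.31 ± 0.24 (SD, n = 3). Its model error of 0.67 takes in the SD of 2.22 in LNCaP overexpression, so the missing call does not show that KLK3 was unchanged.

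In the lists, again as arrays labelled ONECUT2 shRNA against arrays labelled scramble, cholesterol and fatty acid genes were higher in 15 of 20 and lower in 0 (median 1.00, adjusted p = 2.36e-09, and adjusted p = 0.215 with an estimated correlation). IDI1 rose by 1.00, DHCR7, the last enzyme of cholesterol synthesis, by 1.08 and LSS, lanosterol synthase, by 1.21. p53 targets were lower in 14 of 19 and higher in 0 (median -0.73, adjusted p = 7.75e-06, and 0.00314 with an estimated correlation). CDKN1A fell by 1.48, TP53INP1 by 1.42 and SPATA18, of mitochondrial quality control, by 2.05. HNF, gut and liver genes were higher in 5 of 11 and lower in 0 (median 0.69, adjusted p = 5.08e-04, and adjusted p = 0.0706 with an estimated correlation). APOH rose by at least 2.36, ALB, serum albumin, by 2.34 and HNF4G by 1.84. Neuroendocrine markers were higher in 6 and lower in 2 of 18 (median 0.41, adjusted p = 0.0271, and adjusted p = 0.255 with an estimated correlation). CHGA rose by 1.73, SCG5, a secretory granule protein, by at least 0.47 and the Notch ligand DLL3 by 1.57. Basal markers were higher in 2 of 3, CD44 by 1.81 (adjusted p = 0.0458, and adjusted p = 0.255 with an estimated correlation), and stress genes higher in 9 and lower in 3 of 24 (adjusted p = 0.0458, and adjusted p = 0.403 with an estimated correlation). PHGDH, of serine synthesis, and ASNS, asparagine synthetase, rose by 0.70 and 0.49. Without the array labelled ONECUT2 shRNA replicate 1, the neuroendocrine, basal and stress calls were lost (adjusted p = 0.0515, 0.0687 and 0.0848). The stress call was also lost without labelled scramble replicate 3 (0.0785) or labelled ONECUT2 shRNA replicate 2 (0.0507), with quantile normalization (0.0501) and with median centring (0.053). Median centring also ended the basal call (0.053), a filter of 6 the neuroendocrine call (0.115), and the basal median was -0.02 without the filter (adjusted p = 0.496). Adjusted over the list alone, 18 cholesterol, 6 HNF and 7 neuroendocrine genes were higher and 3 neuroendocrine genes lower.

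The remaining lists described did not pass between the arrays labelled ONECUT2 shRNA and those labelled scramble. HOXB13, a prostate homeobox factor, rose by 0.94, and FOXA1 differed by -0.08 ± 0.50 (adjusted p = 0.928). Luminal markers counted 4 higher and 5 lower of 15 (adjusted p = 0.841), with DPP4, a peptidase, up by 1.60. Neuronal genes counted 5 and 1 of 17 (0.12), G1-S genes 4 and 2 of 24 (0.13), interferon-stimulated genes 3 and 2 of 21 (0.841), and hypoxia genes 3 and 5 of 24 (0.687). NEFL rose by at least 0.42, IFIH1, a sensor of viral RNA, rose by 2.25, HERC5 fell by 1.83 and ADM fell by 2.09. TGF-beta genes counted 3 and 5 of 16 (0.461), transition genes 4 and 4 of 15 (0.461) and stromal markers 0 and 2 of 5 (0.13). TNC, tenascin C, rose by 2.19, MET, the hepatocyte growth factor receptor, rose by at least 2.04, and LUM, the proteoglycan lumican, fell by 3.33. Adjusted over the list alone, 6 TGF-beta genes were lower, and 1 of the G1-S genes, with other counts the same. PEG10 differed by 0.05 ± 0.25 (adjusted p = 0.914), and its sign turned without labelled scramble replicate 2 (-0.0063).

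Overexpression and the labelled shRNA comparison in 22Rv1 share no array, and the genes they both called went in opposite directions more often than in the same one. Among the largest opposite changes, these fell with overexpression and were higher in the arrays labelled ONECUT2 shRNA: CYP2C8 (-3.87 and 4.59), LGR5 (-2.80 and 4.04), APOH (lower by at least 2.15 and higher by at least 2.36), the RNA editing factor A1CF (-2.61 and 2.58) and GCG, proglucagon (-3.12 and 2.56). CDH6, ASB9, of a ubiquitin ligase, and ADRA2A were the other leading genes of that kind. H2AC6 (5.35 and -5.36) and H2BC21 (5.15 and -4.22) did the reverse. SQOR, of sulfide oxidation, the zinc transporter SLC30A4, the xenobiotic enzyme CYP1A1, H2BC12L, CGA and ADM also rose with overexpression and were lower in the arrays labelled ONECUT2 shRNA. Against the 22Rv1 control, the arrays labelled ONECUT2 shRNA gave no call for CYP2C8 (0.47), LGR5 (0.72), APOH (0.21), A1CF (0.25) or GCG (0.55). The arrays labelled scramble were lower than that control for CYP2C8 (-4.12), LGR5 (-3.32), A1CF (-2.33), GCG (-2.01) and APOH (3.33 against 6.15). For these genes the opposite direction thus rests on the arrays labelled scramble. H2AC6 and H2BC21 differed from control in both labelled groups (-2.33 and -1.70 for ONECUT2 shRNA, 3.03 and 2.52 for scramble). Of 2485 genes called in both, 1558 (62.7%) were opposite and 927 the same. Rises paired with lower values in 1002 genes, where independent lists would share 717 (one-sided Fisher exact p = 5.46e-47), and falls with higher values in 556, against 396 (one-sided Fisher exact p = 3.7e-22). Across all genes the Pearson correlation was -0.0922 and the Spearman correlation -0.125. ONECUT2 messenger RNA was higher in both comparisons, against the label of the shRNA arrays, and the beta-actin (8.06 against 4.11) and ribosomal RNA (5.50 against 8.93) differences go with the overexpression values. The ribosomal RNA control ran the opposite way in the labelled shRNA comparison (9.17 against 7.47), as the opposite genes did.

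The control groups of 22Rv1 also differed from each other. The arrays labelled scramble had 1516 genes higher and 1143 lower than the 22Rv1 control, 2659 in all and 519 by at least 2-fold. GRM3, a glutamate receptor, rose by 4.19 ± 0.18, ASZ1 by at least 3.73, H1-2 by 3.66 and BASP1 by 3.51, and KLK3 was higher by 2.73 (adjusted p = 0.0088). CYP2C8 fell by 4.12 ± 0.21, LGR5 by 3.32, ADRA2A by 3.25, the nuclear noncoding RNA MALAT1 by 3.07 and RBM47, an RNA-binding protein, by 3.03. Lists lower by camera were HNF, gut and liver (adjusted p = 3.53e-04), neuroendocrine (0.0107), cholesterol (0.0107), stress (0.0109), basal (0.0375) and neuronal (0.043). All 6 calls were lost, with adjusted p = 0.085, 0.267, 0.492, 0.347, 0.335 and 0.145 with an estimated correlation. Centring moved the share of higher calls from 57.0% to 43.7%. The 5' control probe set of ribosomal RNA was 7.47 ± 0.19 in the arrays labelled scramble against 8.93 ± 0.19 in control (SD, n = 3), which goes with these lists and genes. The middle and 3' ones were lower as well (6.84 against 8.38, and 5.90 against 7.34).

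Between the lines, LNCaP control and 22Rv1 control differed in 7736 genes, 3668 higher and 4068 lower in LNCaP, 3312 by at least 2-fold. The share higher moved from 47.4% to 50.8% when arrays were centred. TM4SF1, the chemokine receptor ACKR3, DNASE2B, RAB25, a small GTPase, and JAG1, a Notch ligand, had the largest fitted rises in LNCaP, TM4SF1 by at least 6.99, RAB25 by at least 6.89, JAG1 by at least 6.47 and DNASE2B by at least 6.10. ID4, an inhibitor of differentiation, was lower by at least 9.80, and RGS2, ALB, PDK4, a pyruvate dehydrogenase kinase, and GJA1 by at least 8.30, 8.75, 7.38 and 7.62. The ribosomal RNA probe set read 13.26 ± 0.31 in LNCaP control against 8.93 ± 0.19. Interferon-stimulated genes were higher in LNCaP for 12 of 21 (adjusted p = 0.0477, and adjusted p = 0.0775 with an estimated correlation). Neuronal genes were lower for 14 of 17 (6.78e-04, and 0.0273 with an estimated correlation). Neuroendocrine markers were lower for 15 of 18 (1.7e-05) and HNF, gut and liver genes for 8 of 11 (3.57e-04). Those calls were lost, with adjusted p = 0.0544 and 0.0544 with an estimated correlation.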

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

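The tests of exchanged and of correct shRNA labels, of 22Rv1 cells as the source of shared rises, of untransduced LNCaP cells and of 5' loss behind shared changes were chosen only after the result was seen. The others were set beforehand.

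ONECUT2 messenger RNA was higher in the arrays labelled ONECUT2 shRNA than in those labelled scramble, while the titles go with the labels: that of the former carries the last digits of an ONECUT2 clone named in the protocol, and that of the latter another number. Correct labels with a working shRNA would need ONECUT2 below the 22Rv1 control in the arrays labelled ONECUT2 shRNA, but no probe set was called lower there: that of the gene comparisons (log2 difference 0.65) and 1 other were higher and 3 of the 5 did not differ, which argues against that account. An exchange of both labels, which would have to hold for the titles as well, may be the source: ONECUT2 was lower in the arrays labelled scramble than in the control (-1.41), and these differed from the control in 2659 genes, against 542 for the arrays labelled ONECUT2 shRNA, although a ribosomal RNA control differed as well (7.47 against 8.93). Against a simple exchange stands the excess of genes changed in opposite directions by overexpression and in the labelled shRNA arrays (1558 against 927), since exchanged labels would turn it into an excess of the same direction, but the ribosomal RNA control moved oppositely in these comparisons too (5.50 against 8.93, and 9.17 against 7.47), so the excess may follow RNA differences and does not settle the labels. Exchange stays open, as does a biological change in ONECUT2 with an shRNA that leaves its messenger RNA in place, which was not tested.

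The LNCaP overexpression arrays correlated more with 22Rv1 overexpression than with 22Rv1 control (means of 0.946 and 0.928 across all probe sets, with 0.947 between the control groups), and more still with LNCaP control (0.957). Untransduced LNCaP cells in replicate 1 are argued against by an interquartile range of 1.46 (log2) over 65 genes that such a mixture would hold at 1 share. A small share of 22Rv1 cells could be present, since only 7.69% of 78 genes specific to 22Rv1 overexpression stayed under 4 on both replicates 2 and 3, although 34 and 30 of them were under 4 on replicates 1 and 2 and ALB read 3.03 on replicate 3 against 10.96 in 22Rv1 overexpression. On replicate 3 these genes lay from -7.92 to 0.46 (log2) off the 22Rv1 overexpression level, with quartiles of -4.99 and -2.68. A mixture would hold them at 1 share, so it alone does not account for all of them. Such cells as the source of the shared rises are argued against by 53.3% of 835 genes rising in both lines by more than 4 times the upper-quartile share, a limit set after the per-array distribution was seen and only just over its bound of 50%. An effect of ONECUT2 common to both lines, the biological explanation the design gives, stays open beside a share of 22Rv1 RNA in replicate 3. The labels do not say whether the control cells, labelled vehicle, carried an empty vector. An effect of the vector in both lines thus cannot be told apart from that of ONECUT2.

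The 5' beta-actin control probe set fell relative to the 3' one in 22Rv1 overexpression, a difference of 3.94 in log2 from a measurement outside the gene comparisons. Loss of 5' sequence as the cause of changes seen in both lines is argued against by 86.6% of the genes called in both going the same way, since LNCaP arrays had no such difference. For the genes called in 22Rv1 alone, 5' loss was not settled. Among genes with several probe sets, 30.1% of 1075 had probe sets that differed by over 1, against 19.4% of 1168 for LNCaP alone. That difference of 10.7 percentage points only just exceeds the 10 set beforehand. The positions of the probe sets were not used, so the test cannot tell 5' loss from any other difference between probe sets. An effect of ONECUT2 on these genes or on actin itself, the biological explanation, was not tested and stays open.

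The effect of overexpression differed between the lines for 5432 genes by the test of the difference, and 676 genes with such a difference changed in opposite directions. LNCaP minus 22Rv1, the difference was 8.58 for MBD3L2, 8.20 for PRAMEF12, 7.03 for PRAMEF11, 6.84 for ALDH5A1 and 6.61 for FRG2EP. It was -7.91 for TM4SF1, -6.84 for DNASE2B, -6.70 for RUNX2, -6.59 for RRM2 and -6.13 for FCAMR. Of these 10 genes 9 had a group mean under 4, and without LNCaP overexpression replicate 1 the difference was 7.88 for FRG2EP, -7.58 for DNASE2B and -7.96 for RRM2, or 5.89 for FRG2EP and -5.66 for RRM2 without replicate 2. Among the lists, the median difference was -3.01 for mitosis, -1.04 for G1-S and replication, 1.84 for HNF, gut and liver, 1.53 for p53 targets and 0.32 for cholesterol synthesis. Several HNF, gut and liver genes, such as SPINK1 and APOH, had means under 4 in both LNCaP groups, so the value of that list rests partly on background. Without LNCaP overexpression replicate 1 or 3 the count was 7556 or 5184. These differences subtract the 22Rv1 effect, whose arrays carry the beta-actin (8.06 against 4.11) and ribosomal RNA (5.50 against 8.93) differences. Among 2569 probe sets without a gene symbol, which the gene comparisons leave out, 1271 changed in 22Rv1 overexpression, 1250 in LNCaP overexpression and 664 between the labelled shRNA groups.

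Other splits of the same arrays were counted for each comparison. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. In each the real split alone (1 of 10) gave as many genes: 7392 for 22Rv1 overexpression (highest other 0), 7557 for LNCaP overexpression (4), 3593 for the labelled shRNA groups (0), 2659 for labelled scramble against control (0) and 7736 between lines (0). For the difference between lines, 3 of 100 drawn splits gave as many as the real 5432. The highest other, 8647, keeps every real group and turns the sign in 1 line, so that it adds the effects of both lines, and the next, 5727, keeps the 22Rv1 groups whole, a structure of the samples. For genes changed in the same direction in both lines, 1 of 100 splits gave the real 4367 (highest other 3), and for opposite changes in overexpression and labelled shRNA 1 of 100 gave 1558 (highest other 0). Other splits of a single comparison left at most 4 calls, so these joint counts were bound to lie near 0. The splits break up the effect of each comparison itself, so they cannot decide whether shared, opposite or differing effects arose by chance.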

How the results depend on the processing

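The 22Rv1 control in place of the arrays labelled scramble was chosen only after the result was seen. It gave 542 genes, against 3593, with other arrays compared. Every probe set on its own (24871 tested) gave 14185 calls in 22Rv1 overexpression, 14371 in LNCaP overexpression, 6594 between the labelled shRNA groups, 10309 for the difference between lines, 7973 the same way in both lines, 2725 opposite in overexpression and labelled shRNA, 5376 for labelled scramble against control and 15733 between lines, since more features were tested. A 2-fold minimum gave, in that order, 2896, 3093, 799, 2605, 1422, 208, 519 and 3312, and adjusted p under 0.01 gave 2278 between the labelled shRNA groups, 928 opposite and 1511 for labelled scramble, both by a stricter limit. Array weights, whose fit gave a convergence warning, gave 6844, 3270 and 6415 for these, and only the groups compared gave 2460 opposite and 4629 for labelled scramble; the cause was not tested. A replicate block on only the groups compared, which changes both choices at once, gave 4867 in LNCaP overexpression, 5702 between the labelled shRNA groups, 2624 opposite and 5495 for labelled scramble. With it PEG10 was called lower in 22Rv1 overexpression (-0.40, adjusted p = 2.86e-04). In LNCaP overexpression the calls of TUBB3, LUM and HNF4G were lost (adjusted p = 0.0517, 0.133 and 0.125). Same-numbered arrays did not all deviate together, and not every array correlated best with its own number. In 22Rv1 overexpression against control their correlations were -0.15, -0.22 and -0.04, but between the line controls 0.06, 0.14 and 0.08. Whether the numbers pair the arrays is thus not settled. With each array left out, the counts ranged from 6698 to 6768, 6888 to 8837, 2761 to 2998, 4868 to 7556, 3993 to 5363, 1208 to 1408, 1864 to 2322 and 7127 to 7201 in the same order, and list calls from 14 to 17. Of 17 list calls in the main comparisons 7 held with an estimated correlation; fry, which compares no list with other genes, called 43 directionally and 50 in either direction. PEG10 between the labelled shRNA groups ranged from -0.0063 without labelled scramble replicate 2 to 0.13, and never passed. Over all alternatives and left-out arrays, named genes gave 39 weaker and 2 stronger results (285 results) and lists 25 weaker (17 results). Counts kept within 1.5 times under the other alternatives, including no filter (19777 genes), a filter of 6 (9378), the mean of probe sets (11039), quantile normalization and median centring. Signal over background limits genes near the filter of 4.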

Other observations

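The test of other DUX4 targets over the filter was set before their values were seen, its count without the filter was chosen after that result, and the genes with opposite changes in the lines were chosen after theirs.

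Some genes moved in opposite directions when ONECUT2 was overexpressed in 22Rv1 and in LNCaP, with a called difference between lines. ID1, an inhibitor of differentiation, fell by 1.69 ± 0.17 in 22Rv1 and rose by 2.02 ± 0.17 in LNCaP (difference 3.71 ± 0.24, adjusted p = 7.95e-09). IDI1, of isoprenoid synthesis, fell by 1.08 ± 0.10 and rose by 1.35 ± 0.10 (difference 2.43 ± 0.15, adjusted p = 4.16e-09). BAX, a p53 target that promotes apoptosis, fell by 1.74 ± 0.21 and rose by 1.26 ± 0.21 (difference 3.00 ± 0.30, adjusted p = 8.18e-07). CCND1, the G1 cyclin D1, fell by 1.06 ± 0.08 and rose by 0.65 ± 0.08 (difference 1.71 ± 0.11, adjusted p = 5.54e-09), apart from the rest of its list, of which 22 of 24 fell in LNCaP. BHLHE40, a hypoxia-responsive transcription factor, rose by 2.44 ± 0.22 in 22Rv1 and fell by 1.52 ± 0.22 in LNCaP (difference -3.96 ± 0.31, adjusted p = 7.75e-08). The beta-actin and ribosomal RNA differences of the 22Rv1 overexpression arrays go with these values as well.

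MBD3L2, PRAMEF11 and PRAMEF12, among the largest rises in LNCaP overexpression, are known targets of DUX4, a transcription factor of early embryos, which may be active in those cells. In a list of 47 DUX4 targets, 19 had a single-symbol probe set, and 6 besides those first seen passed the filter. Of these, 5 were called higher in LNCaP overexpression: RFPL3 by 1.57 ± 0.13, RFPL2 by 1.33 ± 0.12, PNMA6A by 1.08 ± 0.20, ZNF217 by 0.54 ± 0.09 and HSPA6 by at least 2.97. KHDC1 differed by 0.10 ± 0.14 (adjusted p = 0.542). A gene silent in the other groups passes the filter only if it rose, so the count was also made without it. There 14 of 16 were higher and 0 lower, against 24.7% higher of all 19777 genes (one-sided Fisher exact p = 2.24e-07), although some of them, such as RFPL1 and TRIM51, read under 4 in both groups. HSPA6, a heat shock gene, read under 4 on replicate 1 but 9.15 and 7.95 on replicates 2 and 3, so replicate 1 did not share its rise, and its fitted change of 3.43 was 5.02 without replicate 1 and 2.34 without replicate 2. In 22Rv1 overexpression 3 of the 6 over the filter were higher as well, where 4440 of all 12159 genes were. MBD3L2 was also called higher there, by at least 0.49 (adjusted p = 1.68e-07), but PRAMEF11 and PRAMEF12 were not (adjusted p = 0.727 and 0.874). As 0 single-symbol probe sets read DUX4 itself, its own level was not tested. The hypothesis rests on few genes, some from multi-copy families, and was prompted by the same arrays.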
